A study of Eulimnogammarus verrucosus and Eulimnogammarus cyaneus and Gammarus lacustris with 24 samples.

How the data were processed

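Whole-body RNA of 3 amphipod species (Eulimnogammarus verrucosus, Eulimnogammarus cyaneus and Gammarus lacustris) was measured by RNA sequencing after 1 month at 1.5 or 12 °C, following 14 days at 6 °C and a gradual change over about 6 days, per the labels. Groups and replicate numbers were taken from the labels, with 4 libraries in each of 6 groups. Each library is a pool of animals, 3 in E. verrucosus, about 13 in E. cyaneus and about 11 in G. lacustris per the labels. The labels name no batch, and all groups share the same collection month.

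Upstream steps were run by the submitters. Reads were assembled per species with Trinity, redundancy was reduced with cd-hit-est, assemblies were filtered with TransRate, and only transcripts with a match to animal proteins were retained, per the series' design text. Salmon 1.1.0 and DESeq2 1.26.0 are named in the submitters' processing notes. The per-library files hold estimated counts per transcript, deposited by the authors and not normalised, per the file headers. They also hold TPM, deposited by the authors, per the file headers, and TPM values were not used in any test. The authors' deposited table of each species holds 1 entry per gene name with a mean normalised count (a signal averaged over all libraries), a log2 fold change with its standard error, a Wald score and p-values, raw and adjusted, per the file headers. The size factors behind the authors' deposited log2 values are not given in the sources used here.

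Estimated counts were rounded to whole numbers. Totals per library were 8501814 to 15417652. The files hold 54473 transcripts for E. verrucosus, 43782 for E. cyaneus and 61366 for G. lacustris, and the 10 most abundant transcripts held between 11.38 and 25.55% of the counts of a library. Number of series columns not used: 0.

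Within each species, 1.5 °C was compared with 12 °C (4 against 4 libraries) by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors and filterByExpr at a minimum count of 10 and a minimum total of 15. Adjustment was by Benjamini-Hochberg over the transcripts tested, at a threshold of 0.05. Fold changes are log2 of 1.5 °C over 12 °C. Principal components and Spearman correlations of log2 CPM (prior count 2) described the spread of libraries. On simulated counts drawn from the real means and library sizes, with 200 transcripts changed, 4-fold changes were recovered for 14.0% of transcripts in E. verrucosus, 56.0% in E. cyaneus and 30.0% in G. lacustris, and 64-fold changes for 95.9% in E. verrucosus and 98.0% in E. cyaneus, and 16-fold changes for 76.0% in E. verrucosus and 96.0% in G. lacustris. Folds of 16 and 64 were added to the simulation after a first run at smaller folds recovered 0 transcripts at 4-fold in E. verrucosus. With so few changed transcripts the adjusted cut is stricter than in the real fits of E. verrucosus and G. lacustris, so their recovered shares do not describe those fits.

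The transcript identifiers of the count files and the gene names of the authors' deposited tables are not paired in the files. A name was given to a transcript, or to every member of a set of transcripts, by its mean normalised count over the 8 libraries. The mean of the transcript, or of the summed set, had to equal the mean in the authors' deposited table within a relative tolerance of 1e-12. This paired 2801 of 3920 names (71.5%) in E. verrucosus, 2830 of 3674 (77.0%) in E. cyaneus and 3351 of 5094 (65.8%) in G. lacustris. Of these, 2268, 2428 and 2850 names rested on 1 transcript. For the others only the summed set equalled the deposited mean, while fold changes are given per transcript. Deposited means shifted by a relative 1e-5 up or down, used as decoys, gave 0 matches. The size factors needed for this were solved by least squares on names that 1 transcript matched, from coarse starting values found while these files were explored. Paired transcripts held 6.8 to 21.1% of the counts of a library, so that gene groups describe that share only.

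Of 29 gene group themes fixed before the data were examined, 28 had names in at least 1 species. Because the tables give symbols and no protein descriptions, members were assigned by symbol after the tables were seen, in place of the description patterns fixed earlier. The test of a list was a 2-sided Fisher's exact test of its positive and negative fold changes against those of the other named transcripts, with Benjamini-Hochberg adjustment over 55 tests of lists with at least 5 members. The fixed design named this split for the entries of the authors' tables. Here it was made on edgeR's fold changes of the paired transcripts instead, and the split of the authors' entries was run as an alternative. It takes members as independent, and correlated members make its p too small. Camera (limma 3.58.1) with a preset correlation of 0.01 and with an estimated correlation, and fry, were run beside it on the same named transcripts after the data were seen. Camera had in fact been run first, and the split was taken as the test of lists only afterwards, because names covered a small share of the counts. Fry tests whether the members move, on balance, one way, and does not compare them with other genes. With an estimated correlation camera called 0 lists in any species, while with the preset value it called 8 in E. verrucosus, 3 in E. cyaneus and 0 in G. lacustris when adjusted within each species, and 4, 3 and 2 when adjusted over the 55 tests. Temperature effects were compared between species with limma on the mean log2 CPM of the members of 14 lists, with Benjamini-Hochberg adjustment over 42 tests.

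Named genes followed a rule fixed before the data were examined. For each species it takes the 8 largest positive and 8 largest negative log2 fold changes among transcripts with an adjusted p under 0.05, a mean of at least 5 CPM, groups that do not overlap and a name that says a function, with 1 transcript per name. It adds up to 3 called members per list by highest mean CPM, and names called in all 3 species, of which there were 0 in edgeR. Genes quoted from the authors' deposited tables are the 8 largest changes each way among entries with a mean normalised count of at least 100 and the 3 called list members of highest mean, a rule written after the tables were seen. Other list members that are named as examples, most of them the members of highest mean CPM, were chosen after their values were seen. Some genes that met these rules are not reported here.

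Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, a filter at 5 CPM, counts summed per assembly gene, offsets from effective lengths, thinning to the smallest total, stricter thresholds (adjusted p 0.001 with an absolute log2 fold change of 3, and a test against a log2 fold change of 1), the replicate number as a block, and leaving out each library in turn. After the data were seen, fits were added without the lower mode of fold changes in G. lacustris (8078 transcripts below the minimum of the density, bandwidth 0.15), with TMM factors from the other transcripts, without the 2 libraries of lowest total in E. verrucosus, without its transcripts under 0.1 CPM at 1 temperature, and with adjustment over named transcripts alone. The motile cilia list was also added after the data were seen. Shares have 95% Wilson intervals, which cover counting error only. Other languages and packages were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.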

Results

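RNA of whole amphipod crustaceans was sequenced from 3 species collected at Bolshie Koty on Lake Baikal, the endemic Eulimnogammarus verrucosus and Eulimnogammarus cyaneus and the widespread Gammarus lacustris. Animals of each species were held at 6 °C, moved gradually to 1.5 or 12 °C and kept there for 1 month. The comparison in each species asks which transcripts differ in level between the cold and the warm animals. Each of the 6 groups had 4 libraries, and each library came from a separate pool of animals (3 animals per pool in E. verrucosus, about 13 in E. cyaneus and about 11 in G. lacustris), so that p-values measure the spread between pools. Totals of estimated counts per library ran from 10187151 to 15417652 in E. verrucosus, 9110157 to 14222364 in E. cyaneus and 8501814 to 10176490 in G. lacustris. Every fold change is given as log2 of 1.5 °C over 12 °C, so that positive values are higher in the cold. Levels are in CPM, counts scaled to a common library total, given as mean ± SD over the 4 pools of a group.

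Each species was quantified on its own transcript assembly. Gene names came from the authors' deposited table of each species and were joined to transcripts through identical mean normalised counts. This gave a name to 1989 of 24119 tested transcripts in E. verrucosus, 1741 of 20678 in E. cyaneus and 2248 of 27194 in G. lacustris. Transcripts of near-identical copies, such as isoforms, tubulins, actins and histones, can share reads, and a value for 1 transcript of such a family is uncertain. Unless the authors' deposited table is named, values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all transcripts tested in that species (n = 4 pools per temperature).

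In E. verrucosus the chaperonin subunit CCT6A, part of the ring complex that folds actin and tubulin, rose from 68.6 ± 11.9 CPM at 12 °C to 196 ± 21.8 CPM at 1.5 °C (log2 fold change 1.51, SE 0.24, edgeR adjusted p = 0.00865). RAB11A, a small GTPase of recycling endosomes, rose from 0.954 ± 0.0919 to 9.1 ± 4.12 CPM (log2 fold change 3.24, SE 0.39, edgeR adjusted p = 0.00234), and smgl-2 rose from 2.28 ± 0.699 to 14 ± 3.98 CPM (2.61, SE 0.36, adjusted p = 0.00427). CCDC124, which encodes a ribosome-binding protein, fell from 37.6 ± 19.7 to 0.176 ± 0.184 CPM (log2 fold change −7.62, SE 0.85, edgeR adjusted p = 0.00184). That fall to near 0 resembles the 380 transcripts under 0.1 CPM at 1.5 °C described below, although its level lies above that limit. Whether CCDC124 shares their source was not tested. The helicase DDX42 fell from 23.8 ± 0.964 to 11.6 ± 1.03 CPM (−1.03, SE 0.19, adjusted p = 0.019), and so did the splicing factor SRSF7 (−1.66, SE 0.31, adjusted p = 0.0182), while of 2 transcripts of the RNA-binding protein HNRNPK 1 rose (1.42, SE 0.24, adjusted p = 0.0105) and the more abundant lay at −0.07 (SE 0.27, adjusted p = 0.973). Lower levels in the cold were also called for the bestrophin BEST3 (−1.65, SE 0.35, adjusted p = 0.0378), the transcription-coupled repair factor UVSSA (−1.05, SE 0.22, adjusted p = 0.0376) and the elongation factor subunit eEF1delta (−4.25, SE 0.92, adjusted p = 0.0429).

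CCT6A, RAB11A, smgl-2 and CCDC124 kept their calls in each of 8 fits that left out 1 library of E. verrucosus. SRSF7 kept its call only without 12 °C replicate 1 (adjusted p = 0.046), 12 °C replicate 3 (0.0201) or 1.5 °C replicate 4 (0.0177), DDX42 only without 12 °C replicate 1 (0.0382) or 1.5 °C replicate 4 (0.0357), BEST3 only without 12 °C replicate 4 (0.0456) and eEF1delta only without 1.5 °C replicate 3 (0.0119), while UVSSA lost its call without any 1 of the 8 libraries (edgeR adjusted p from 0.0564 to 0.129). In the other fits edgeR's adjusted p reached 0.068 for SRSF7, 0.0826 for DDX42, 0.115 for BEST3 and 0.123 for eEF1delta.

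**Figure D1:**
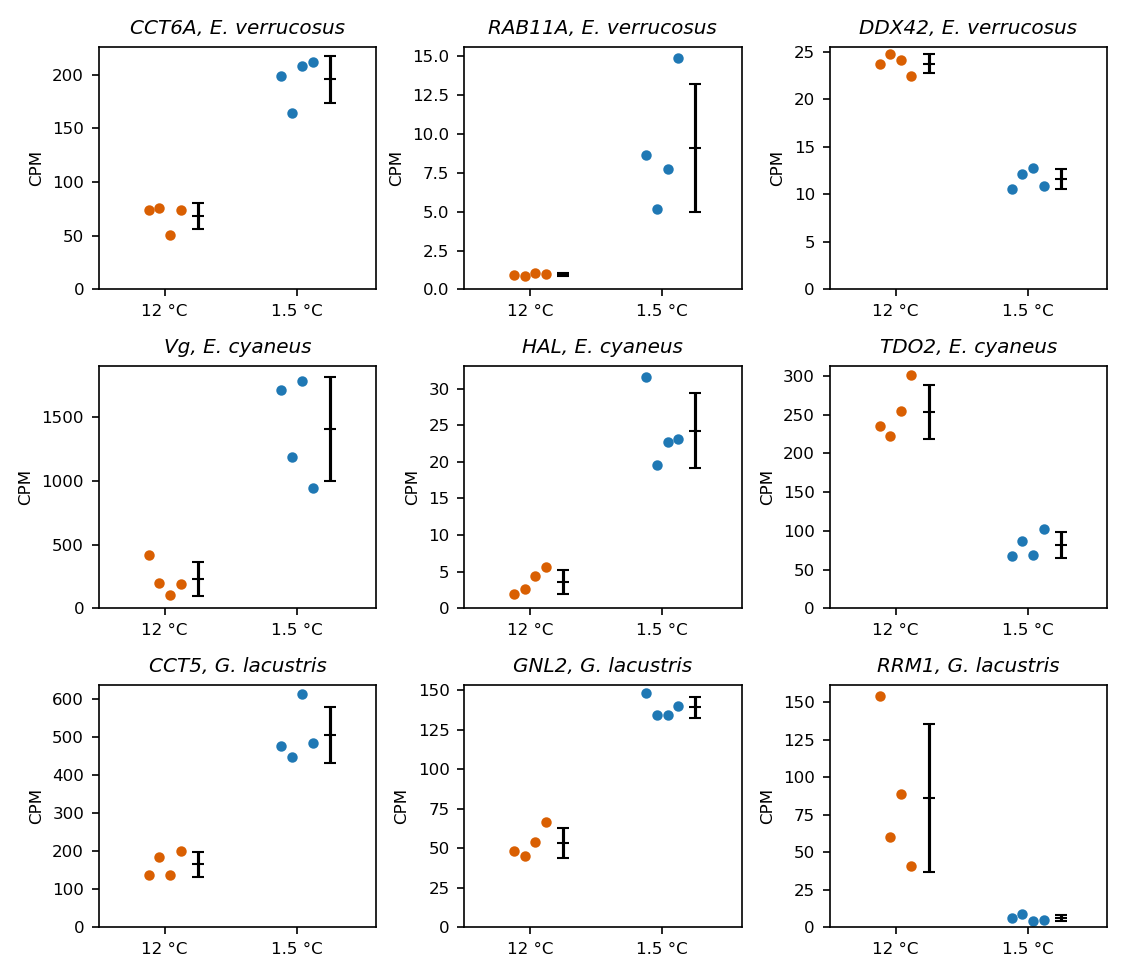
Level of 9 named transcripts in each library, in CPM, with 3 transcripts for each species; dots are single pools and the bars give the mean ± SD of the 4 pools at 12 and 1.5 °C. In E. verrucosus CCT6A lay at 68.6 CPM at 12 °C and 196 CPM at 1.5 °C, in E. cyaneus Vg lay at 229 and 1407 CPM, and in G. lacustris CCT5 lay at 166 and 505 CPM.

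Translation factors and ribosome biogenesis proteins of E. verrucosus leaned to higher levels in the cold. Of their 47 named transcripts, 35 had a positive and 12 a negative fold change, against 960 and 982 of the other named transcripts (Fisher's exact test, adjusted p = 0.0174, and adjusted p = 0.468 in camera with an estimated correlation), with a median log2 fold change of 0.34. Among these members 0 rose, 1 fell (eEF1delta) and 46 did not pass in edgeR. Adjusted over the list alone, 0 passed, while 7 had an unadjusted p under 0.05 and DESeq2 called 2. Examples are NOB1, an endonuclease of small-subunit maturation (0.70, SE 0.22, adjusted p = 0.202), and NMD3, an export adapter of the large subunit (0.54, SE 0.22, adjusted p = 0.372). In the authors' deposited table, FBL, the methyltransferase fibrillarin, was higher in the cold by log2 0.96 (SE 0.24, adjusted p = 0.00394), as was GAR1 by 1.03 (SE 0.26, adjusted p = 0.00507). The list call was lost without 1.5 °C replicate 4 (adjusted p = 0.0584) and kept without each of the other 7 libraries.

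The proteasome and ubiquitin list of E. verrucosus had 24 positive and 8 negative members among 32 (median log2 fold change 0.31, Fisher's exact test, adjusted p = 0.0439, and adjusted p = 0.355 with an estimated correlation). None of these members passed in edgeR over all transcripts or adjusted over the list alone (0 in each), 1 had an unadjusted p under 0.05 and DESeq2 called 1. PSMD6, a lid subunit of the proteasome, lay at 0.71 (SE 0.24, adjusted p = 0.257), and in the authors' deposited table PSMC1, an ATPase of its base, was higher in the cold by log2 0.85 (SE 0.24, adjusted p = 0.017) and the deubiquitinase PSMD14 lower at −1.32 (SE 0.36, adjusted p = 0.00794). Without 12 °C replicate 2, 12 °C replicate 4 or 1.5 °C replicate 4 the list did not pass (Fisher's exact test, adjusted p = 0.0574, 0.13 and 0.117).

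Chaperones of E. verrucosus had 8 positive and 4 negative members among 12, a median log2 fold change of 0.37 and a direction split that did not pass (Fisher's exact test, adjusted p = 0.626). Camera gave the list as higher in the cold with a preset correlation (adjusted p = 0.0111) but not with an estimated correlation (adjusted p = 0.355). Fry, which does not compare with other genes, also gave it as higher (adjusted p = 0.00138). CCT6A rose, 0 fell and 11 did not pass over all transcripts, and 5 rose when adjusted over the list alone. The other members that passed over the list alone included the Hsp70 family member hspa8 (0.93, SE 0.30), the chaperonin subunit cct7 (0.89, SE 0.26) and the ribosome-associated co-chaperone DNAJC2 (0.70, SE 0.20). The authors' deposited table listed CCT8L2 as higher in the cold by log2 1.06 (SE 0.23), CCT2 by 0.90 (SE 0.21) and cct7 by 0.87 (SE 0.27).

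Muscle and respiratory chain transcripts of E. verrucosus leaned to lower levels in the cold. Of 14 muscle contractile transcripts 12 were negative (median −0.66, Fisher's exact test, adjusted p = 0.0439, and adjusted p = 0.537 with an estimated correlation). In edgeR 0 rose, 0 fell and 14 did not pass, 0 passed adjusted over the list alone, 2 had an unadjusted p under 0.05 and DESeq2 called 0. The most abundant myosin heavy chain transcript, Mhc1, lay at 19366 ± 15288 CPM at 12 °C and 10258 ± 6828 CPM at 1.5 °C (−0.92, SE 0.69, adjusted p = 0.737). The titin-related kinase Unc-89 lay at −0.88 (SE 0.40, adjusted p = 0.466), and in the authors' deposited table the titin relative sls was lower in the cold at log2 −1.11 (SE 0.36, adjusted p = 0.0481). This list passed only without 12 °C replicate 2 (Fisher's exact test, adjusted p = 0.0399), 12 °C replicate 4 (0.0379) or 1.5 °C replicate 4 (0.0434), and its median was −0.39 without 12 °C replicate 1. Of 24 oxidative phosphorylation transcripts 19 were negative (median −0.27, Fisher's exact test, adjusted p = 0.0351, and adjusted p = 0.793 with an estimated correlation). In edgeR 0 rose, 0 fell and 24 did not pass, 0 passed adjusted over the list alone, 0 had an unadjusted p under 0.05 and DESeq2 called 0. Examples are the mitochondrially encoded oxidase subunits COX2 (−0.52, SE 0.69) and COX3 (−0.35, SE 0.45). Among the 8 fits that left out 1 library, this list passed only without 12 °C replicate 4 (adjusted p = 0.017) or 1.5 °C replicate 4 (0.0056), and its median shrank to −0.10 without 12 °C replicate 1, −0.18 without 12 °C replicate 3 and −0.15 without 1.5 °C replicate 3.

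Over all transcripts of E. verrucosus, edgeR called 805 of 24119, with 319 higher and 486 lower at 1.5 °C. A group mean under 0.1 CPM at 1 of the temperatures was found for 455 of these (56.5%), 380 of them at 1.5 °C and 75 at 12 °C. The 380 held 0.260, 0.658, 0.252 and 0.423% of the counts of the 12 °C libraries and at most 0.001% in any 1.5 °C library, and 1 of them had a name. When the 455 were left out, a selection made on the outcome after the data were seen, 196 transcripts were called, 148 higher and 48 lower. In simulated counts for E. verrucosus the same test recovered 14.0% of transcripts changed 4-fold and 76.0% of those changed 16-fold. The 95% Wilson intervals of these shares of a library's counts were at most 0.0093 percentage points wide, which covers counting error only.

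**Figure D2:**
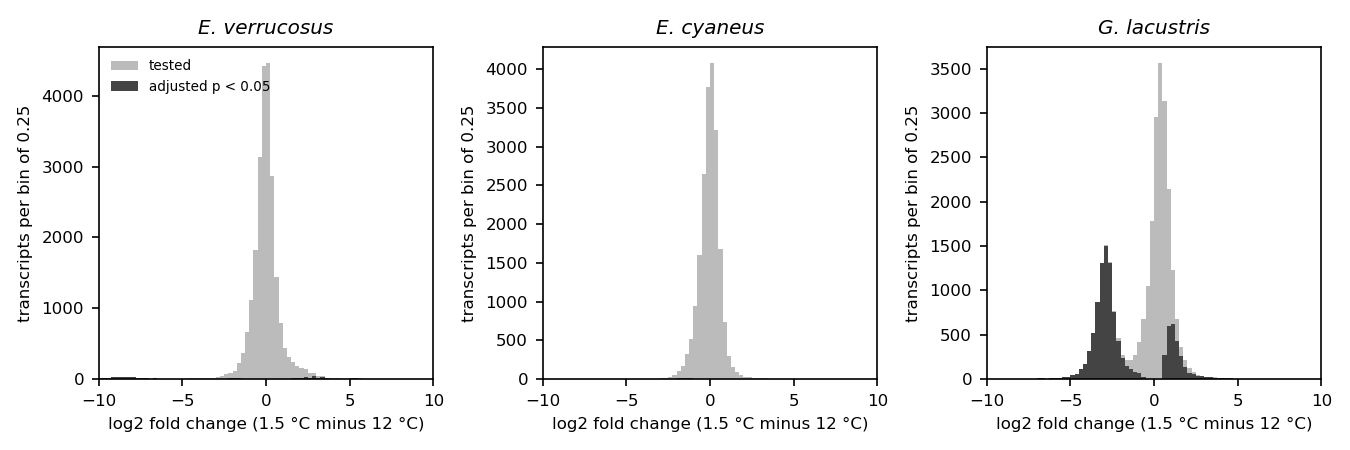
Distribution of the log2 fold change (1.5 °C over 12 °C) of all tested transcripts in each species. The counts of E. verrucosus and E. cyaneus peak near 0, with a far smaller rise in E. verrucosus to 33 transcripts per bin at −8.75 and −8.25, and those of G. lacustris have peaks at −2.88 and 0.40 with a minimum at −1.51 between them.

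In E. cyaneus the yolk protein precursor vitellogenin (Vg) rose from 229 ± 135 CPM at 12 °C to 1407 ± 407 CPM at 1.5 °C (log2 fold change 2.62, SE 0.42, edgeR adjusted p = 0.0295). HAL, histidine ammonia-lyase of histidine breakdown, rose from 3.65 ± 1.64 to 24.2 ± 5.14 CPM (2.71, SE 0.34, adjusted p = 0.00911). TDO2, the tryptophan dioxygenase that opens the kynurenine pathway, fell from 253 ± 34.3 to 81.6 ± 17.1 CPM (−1.63, SE 0.22, adjusted p = 0.0114). The tubulin betaTub56D fell from 70 ± 12.7 to 23.2 ± 4.14 CPM (−1.59, SE 0.22, adjusted p = 0.0149), the GABA receptor subunit GABRB2 from 28.7 ± 3.2 to 14.2 ± 0.88 CPM (−1.02, SE 0.18, adjusted p = 0.0433) and DTD1, which removes D-amino acids from transfer RNA, from 49.8 ± 16.1 to 19.8 ± 1.45 CPM (−1.33, SE 0.25, adjusted p = 0.0495).

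HAL kept its call in each of 8 fits that left out 1 library of E. cyaneus, and TDO2 lost it without 1.5 °C replicate 3 (edgeR adjusted p = 0.0576). Vg and GABRB2 passed only without 12 °C replicate 1 (0.0137 and 0.0302), DTD1 only without 12 °C replicate 1 (0.0306) or replicate 4 (0.0391), and betaTub56D only without 12 °C replicate 1 (0.0137), 12 °C replicate 4 (0.0319) or 1.5 °C replicate 4 (0.0322), with edgeR's adjusted p otherwise reaching 0.088 for Vg, 0.151 for GABRB2, 0.14 for DTD1 and 0.0636 for betaTub56D.

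All 11 muscle contractile transcripts of E. cyaneus had negative fold changes, against 948 positive and 782 negative of the other named transcripts (median −1.07, Fisher's exact test, adjusted p = 0.00927, and adjusted p = 0.355 in camera with an estimated correlation). Over all transcripts 0 rose, 0 fell and 11 did not pass in edgeR, although 8 had an unadjusted p under 0.05, 8 fell when adjusted over the list alone, and DESeq2 called 3. The myosin light chain Mlc2 lay at 6616 ± 3434 CPM at 12 °C and 2632 ± 894 CPM at 1.5 °C (−1.33, SE 0.41, adjusted p = 0.183), the thin-filament protein troponin I (TNNI1) at 4471 ± 1613 and 2343 ± 731 CPM (−0.93, SE 0.33, adjusted p = 0.235), and sls at 392 ± 121 and 186 ± 20.1 CPM (−1.07, SE 0.24, adjusted p = 0.0909). In the authors' deposited table Mlc2 (log2 −1.43, SE 0.34, adjusted p = 0.00174), Unc-89 (−1.49, SE 0.41, adjusted p = 0.011) and TNNI1 (−1.04, SE 0.31, adjusted p = 0.0195) were called lower in the cold. Without any 1 library the list still passed (Fisher's exact test, adjusted p from 0.00291 to 0.0229). In 12 °C replicate 1, 10 transcripts held 25.55% of all counts, and without that library the muscle median was −0.87.

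Respiratory chain and ribosomal proteins of E. cyaneus also leaned to lower levels in the cold. Of 16 oxidative phosphorylation transcripts 14 were negative (median −0.41, Fisher's exact test, adjusted p = 0.0174, and adjusted p = 0.601 with an estimated correlation). In edgeR 0 rose, 0 fell and 16 did not pass, 0 passed adjusted over the list alone, 6 had an unadjusted p under 0.05 and DESeq2 called 0. The oxidase subunits COX5A (−0.77, SE 0.29, adjusted p = 0.257) and COX6C (−0.79, SE 0.28, adjusted p = 0.245) are examples, and the authors' deposited table called both lower in the cold (log2 −0.85, SE 0.25, and −0.86, SE 0.26). Without 12 °C replicate 1, 12 °C replicate 4, 1.5 °C replicate 2 or 1.5 °C replicate 3 the list did not pass (Fisher's exact test, adjusted p = 0.0701, 0.0576, 0.058 and 0.0579). Of 36 cytosolic ribosomal protein transcripts 26 were negative (median −0.39, Fisher's exact test, adjusted p = 0.0209, and adjusted p = 0.792 with an estimated correlation). In edgeR 0 rose, 0 fell and 36 did not pass, 0 passed adjusted over the list alone, 9 had an unadjusted p under 0.05 and DESeq2 called 1. RPL14 lay at 1622 ± 344 and 1177 ± 191 CPM (−0.46, SE 0.22, adjusted p = 0.384), and the stalk protein RPLP2 at 996 ± 331 and 544 ± 114 CPM (−0.87, SE 0.27, adjusted p = 0.192). Without 12 °C replicate 1 or 1.5 °C replicate 4 this list did not pass (Fisher's exact test, adjusted p = 0.285 and 0.0714), with medians of −0.21 and −0.49.

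Of 2 yolk and germ line transcripts in E. cyaneus Vg rose and 1 did not pass, and among 11 microtubule transcripts (median −0.48) 0 rose, betaTub56D fell and 10 did not pass, with 2 transcripts at an unadjusted p under 0.05 and 1 called by DESeq2. The authors' deposited table called further single genes: SCD, a fatty acid desaturase, was higher in the cold by log2 0.81 (SE 0.18, adjusted p = 6.0e-04), the acute-phase protein SAA1 by 1.57 (SE 0.40, adjusted p = 0.00399) and the Hsp90 co-chaperone FKBP4 by 1.01 (SE 0.14, adjusted p = 1.2e-10). The same authors' deposited table gave the opsin OPN4 as lower at −2.16 (SE 0.43, adjusted p = 7.7e-05), the cuticle protein CPR23 at −1.93 (SE 0.40, adjusted p = 1.7e-04) and the glycine receptor GLRA3 at −1.25 (SE 0.22, adjusted p = 1.7e-06). Chaperones of E. cyaneus were split evenly (11 positive and 10 negative of 21, median 0.03). In edgeR 0 of these chaperones rose and 0 fell over all transcripts, 5 had an unadjusted p under 0.05, 2 passed adjusted over the list alone (1 rose and 1 fell) and DESeq2 called 2, with cct7 at 0.82 (SE 0.18, adjusted p = 0.0818).

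Over all transcripts of E. cyaneus, edgeR called 130 of 20678, with 65 higher and 65 lower at 1.5 °C, while 2936 had an unadjusted p under 0.05 and DESeq2 called 879. The count fell to 49 and 46 without 12 °C replicates 2 and 3 and to 60, 73, 41 and 58 without 1.5 °C replicates 1 to 4, and it was 197 without 12 °C replicate 1, which stood apart on the first principal component at −134.1. In simulated counts for E. cyaneus the test recovered 56.0% of transcripts changed 4-fold and 98.0% of those changed 64-fold.

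In G. lacustris the chaperonin subunit CCT5 rose from 166 ± 32.1 CPM at 12 °C to 505 ± 73.4 CPM at 1.5 °C (log2 fold change 1.61, SE 0.22, edgeR adjusted p = 4.0e-04), and GNL2, a GTPase of large-subunit assembly, rose from 53.4 ± 9.65 to 139 ± 6.57 CPM (1.38, SE 0.20, adjusted p = 5.2e-04). The ribosomal protein paralog RPS27L rose from 29.8 ± 14.3 to 143 ± 11.7 CPM (2.26, SE 0.38, adjusted p = 8.5e-04), the transcription factor CEBPA from 13.7 ± 4.6 to 53.8 ± 15.6 CPM (1.97, SE 0.32, adjusted p = 6.9e-04), the trehalose synthesis enzyme Tps1 from 220 ± 47.6 to 550 ± 48.6 CPM (1.32, SE 0.22, adjusted p = 7.5e-04) and CPT1A, the gate of fatty acid entry into mitochondria, from 18.8 ± 5.6 to 46.9 ± 8.09 CPM (1.32, SE 0.28, adjusted p = 0.00302). Further rises by the fixed rule were LENG9 (4.40, from 1.83 ± 0.93 to 39.6 ± 50.2 CPM, and 3.14 without 1.5 °C replicate 2), CDK3 (2.45), the spliceosome protein snrpd2 (1.78), LRRFIP2 (1.76) and RpS27 (1.71). The names snrpd2 and RpS27 had 2 tested transcripts each and LRRFIP2 had 3, and these values are of the most abundant. In the authors' deposited table RpS27 lay at log2 2.27, while another entry of that name in different letter case lay at −2.04. The largest named falls were NFE2L1 (−4.50), PLB1 (−4.26), the copper transporter ATP7A (−4.25), Moxd2 (−4.05), STOM (−3.92), LGALS4 (−3.90), the ciliary protein ENKUR (−3.80) and RRM1, the large subunit of ribonucleotide reductase, which fell from 86 ± 49.3 to 6.16 ± 2 CPM (−3.80, SE 0.44, adjusted p = 2.9e-04).

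These falls belong to a set of transcripts that moved together. Fold changes in G. lacustris had peaks at −2.88 and 0.40, and the 8078 transcripts below the minimum at −1.51 are called the lower mode here; it holds all 8 of the largest named falls. The lower mode took 18.6, 11.8, 14.6 and 10.4% of the counts of the 12 °C libraries and 2.3, 2.7, 1.8 and 1.9% at 1.5 °C (95% Wilson intervals at most 0.0498 percentage points wide). Of the 10824 transcripts that edgeR called out of 27194 in G. lacustris, 2639 were higher and 8185 lower at 1.5 °C, and 7904 of the lower ones lay in the lower mode. Without the lower mode, a selection made on the outcome after the data were seen, 339 of 19050 were called, 217 higher and 122 lower. With TMM factors taken from the other transcripts the median log2 fold change was −0.31 in place of 0.11, and 9577 were called, 8.0% of them higher in place of 24.4%. Of the 19116 transcripts outside the lower mode, those factors called 763 higher and 860 lower. Under those factors CCT5 (1.19), GNL2 (0.96), RPS27L (1.87), CEBPA (1.57), Tps1 (0.90) and CPT1A (0.91) kept their calls, and without the lower mode CCT5 (edgeR adjusted p = 0.0172), GNL2 (0.0314), RPS27L (0.0326) and CEBPA (0.03) kept them while Tps1 (0.0585) and CPT1A (0.0942) did not. LENG9 (4.08, adjusted p = 0.0734), CDK3 (2.07, 0.0652), snrpd2 (1.39, 0.0572), LRRFIP2 (1.35, 0.0603) and RpS27 (1.32, 0.0692) also lost their calls without the lower mode, while with TMM factors from the other transcripts they kept them at the same folds (adjusted p = 0.00499, 0.00596, 0.0047, 0.00574 and 0.00601).

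**Figure D3:**
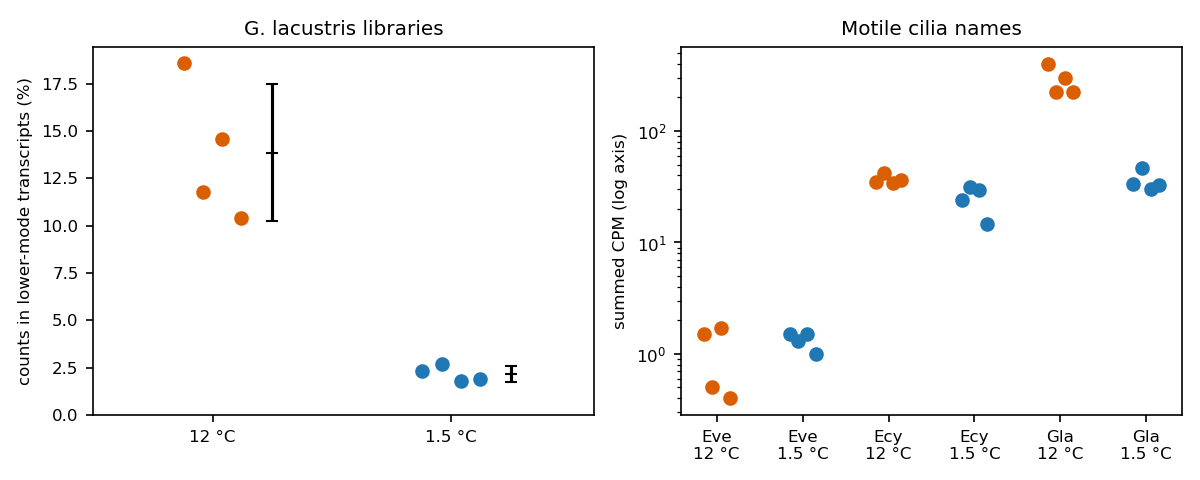
Left, percent of the counts of each G. lacustris library in the lower mode of fold changes; right, summed CPM of named motile cilia transcripts in every library on a log axis (39 names in G. lacustris, 26 in E. cyaneus and 6 in E. verrucosus). Dots are single pools and bars the mean ± SD of 4 pools. The 12 °C libraries of G. lacustris lie between 10.4 and 18.6% on the left and between 223.5 and 401.6 CPM on the right, above 1.8 to 2.7% and 30.2 to 46.9 CPM at 1.5 °C.

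Proteasome and ubiquitin transcripts of G. lacustris had 8 positive and 30 negative members among 38, 29 of them in the lower mode (median −2.68, Fisher's exact test, adjusted p = 0.0351, and adjusted p = 0.792 with an estimated correlation). Of these, 5 rose, 29 fell and 4 did not pass, and adjusted over the list alone 6 rose and 29 fell. The rises of PSMD8 (0.59), PSMB1 (0.74) and UBE2Q1 (1.05) lost their calls with factors from the transcripts outside the lower mode (0.18, 0.31 and 0.66, adjusted p = 0.567, 0.425 and 0.166). They were also lost without 12 °C replicate 3 (adjusted p = 0.074, 0.114 and 0.0528), PSMD8 and PSMB1 without 1.5 °C replicate 3 (0.053 and 0.0504), and PSMD8 and UBE2Q1 without 1.5 °C replicate 4 (0.0611 and 0.0536). PSMD11 (−3.27) and PSMB4 (−2.96), subunits of the lid and the core, fell. The lower mode is defined by its fold changes, so leaving it out takes away 29 of the 30 negative members by construction; the 9 others had a median of 0.33 (Fisher's exact test, adjusted p = 0.405). Oxidative phosphorylation had 6 positive and 28 negative members among 34, 14 of them in the lower mode (median −0.30, mean −1.25, Fisher's exact test, adjusted p = 0.0196, and adjusted p = 0.85 with an estimated correlation). In edgeR 0 rose, 14 fell and 20 did not pass, with the same counts adjusted over the list alone and by DESeq2, and 0 rose at an unadjusted p under 0.05. One transcript of the oxidase subunit COX1, in the lower mode, fell from 11645 ± 9226 to 1629 ± 425 CPM (−2.84, SE 0.48, adjusted p = 9.0e-04), while the other COX1 transcript lay at 0.68 (SE 0.41, adjusted p = 0.228). In the authors' deposited table, whose log2 values lie higher than edgeR's, the oxidative phosphorylation list had 26 positive and 19 negative names of 45. Its median there was 0.35, and the split did not pass (Fisher's exact test, adjusted p = 0.362). Without the lower mode the list kept its direction in edgeR, with 16 of 20 members negative (median −0.58, Fisher's exact test, adjusted p = 0.0199, and adjusted p = 0.608 with an estimated correlation). Leaving out 1 library of all transcripts ended its call except without 12 °C replicate 4 (adjusted p = 0.0281), with values up to 0.809 without 1.5 °C replicate 1, where the median shrank to −0.06; it was −0.13 without 1.5 °C replicate 2 and −0.19 without 12 °C replicate 1 or 1.5 °C replicate 4.

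Translation factors and ribosome biogenesis proteins of G. lacustris had 27 positive and 23 negative members among 50, 22 of them in the lower mode, and their median (0.31) and mean (−0.74) differed in sign. Of these, 14 rose, 22 fell and 14 did not pass, and adjusted over the list alone 16 rose and 22 fell; the split did not pass (Fisher's exact test, unadjusted p = 0.195). Besides GNL2, rises were called for EIF3L (0.86, SE 0.21, adjusted p = 0.00621) and EIF6, which keeps ribosomal subunits apart (0.87, SE 0.20, adjusted p = 0.00479), and both calls were lost with factors from the transcripts outside the lower mode (0.44 and 0.45). Without the lower mode 24 of 28 members were positive (median 0.40, Fisher's exact test, adjusted p = 0.0117, and adjusted p = 0.485 with an estimated correlation), where 2 rose and 3 rose when adjusted over the list alone. Leaving out the lower mode takes away 22 of the 23 negative members by construction, so this split does not test the list as a whole. Cytosolic ribosomal proteins had 15 positive and 24 negative members among 39, 23 of them in the lower mode (median −2.77), and 5 rose, 23 fell and 11 did not pass. RpS3 (0.80) rose, and RpL36A (−3.80) and RPL4 (−3.22) fell. The call of RpS3 was lost with factors from the transcripts outside the lower mode (0.36, adjusted p = 0.283).

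Chaperones of G. lacustris had 4 members that rose, 9 that fell and 9 that did not pass among 22, 9 of them in the lower mode (median −0.61), with HSPA14 at 0.72 (SE 0.19, adjusted p = 0.0116) and the mitochondrial Hsp70 HSPA9 at −2.51 (SE 0.33, adjusted p = 3.7e-04). The rise of HSPA14 did not pass with factors from the transcripts outside the lower mode (0.29). Microtubule proteins had 10 of 14 members that fell and 0 that rose (median −2.62; 0 rose at an unadjusted p under 0.05 and 0 by DESeq2), 10 of them in the lower mode, among them the dynein heavy chain dnah7 of cilia (−3.42) and the light chain DYNLL2 (−3.48). Citrate cycle enzymes (1 rose, 5 fell, 2 did not pass; OGDHL −3.70, IDH3A −2.96), lipid metabolism (2 rose, 9 fell, 4 did not pass; FADS2 −3.02, ACSL5 −3.36) and the cell cycle list (5 rose, 17 fell, 23 did not pass; PLK1 −3.07, MCM3 −2.83) held 5, 9 and 17 lower-mode transcripts, the same numbers as fell. Of 14 muscle transcripts 0 rose, 8 fell and 6 did not pass, 7 of them in the lower mode, such as TNNT2 (−3.19). The abundant TNNI1, outside it, fell from 3691 ± 1000 to 2273 ± 454 CPM (−0.70, SE 0.24, adjusted p = 0.0402), a call kept only without 12 °C replicate 3 (0.0408) or 1.5 °C replicate 3 (0.0429) among 8 fits, with a fold of −0.41 without 1.5 °C replicate 1, and lost without the lower mode (−1.15, adjusted p = 0.0794), while with TMM factors from the other transcripts it passed at −1.15 (adjusted p = 0.00779).

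Of all named transcripts of G. lacustris 45.2% lay in the lower mode. The share was lower, with a 95% Wilson interval below that value, for immune and hemocyte proteins (1 of 24, up to 20.2%), detoxification enzymes (3 of 16, up to 43.0%) and cuticle proteins (0 of 6, up to 39.0%), while small lists such as vision (0 of 4, up to 49.0%) do not tell. Of the immune transcripts 2 rose (the protease inhibitor SERPINB1, 1.03, and CLEC16A, 1.50), 2 fell (the galectin LGALS4, −3.90, and the lysozyme LYSC6, −1.36) and 20 did not pass, and adjusted over the list alone 1 fell. SERPINB1 lost its call without 12 °C replicate 3 (edgeR adjusted p = 0.0765) or 1.5 °C replicate 3 (0.0507) and with factors from the transcripts outside the lower mode (0.145), and LYSC6 passed only without 12 °C replicate 2, with adjusted p otherwise reaching 0.159 without 1.5 °C replicate 1 and the fold shrinking to −0.74 without 12 °C replicate 1. The authors' deposited table held more names and gave 23 of 29 immune names as higher in the cold (Fisher's exact test, adjusted p = 0.00383), among them A2ML1 at log2 0.93 (SE 0.26, adjusted p = 0.00103). The log2 values of the authors' deposited table lie higher than edgeR's in G. lacustris (median difference −0.65, edgeR minus the table), which moves the point where signs change. In edgeR's values the same list had 14 positive and 10 negative transcripts and did not pass (Fisher's exact test, adjusted p = 0.438, and adjusted p = 0.462 with an estimated correlation), while camera with a preset correlation gave it as higher in the cold (adjusted p = 0.0409). Detoxification enzymes had 0 that rose, 2 that fell (MGST1 −3.51 and CYP17A1 −3.37, both in the lower mode) and 14 that did not pass, with 1 positive member at an unadjusted p under 0.05 and 0 called higher by DESeq2. Without the lower mode 11 of 13 detoxification transcripts were negative (median −0.74, Fisher's exact test, adjusted p = 0.0428, and adjusted p = 0.363 with an estimated correlation), where 0 passed in edgeR over all transcripts and 6 fell when adjusted over the list alone. The 6 cuticle transcripts (median 0.12) and 4 vision transcripts (median 0.66) had 0 calls in edgeR, 0 at an unadjusted p under 0.05 and 0 by DESeq2. With the replicate block edgeR called 1 of each list higher in the cold. The authors' deposited table called the arrestins Arr1 (log2 1.75, SE 0.51, adjusted p = 0.00151) and Arr2 (1.27, SE 0.34, adjusted p = 6.9e-04) higher in the cold, as well as the cuticle list member Cpap3-a1 (1.14, SE 0.33, adjusted p = 0.00129).

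**Figure D4:**
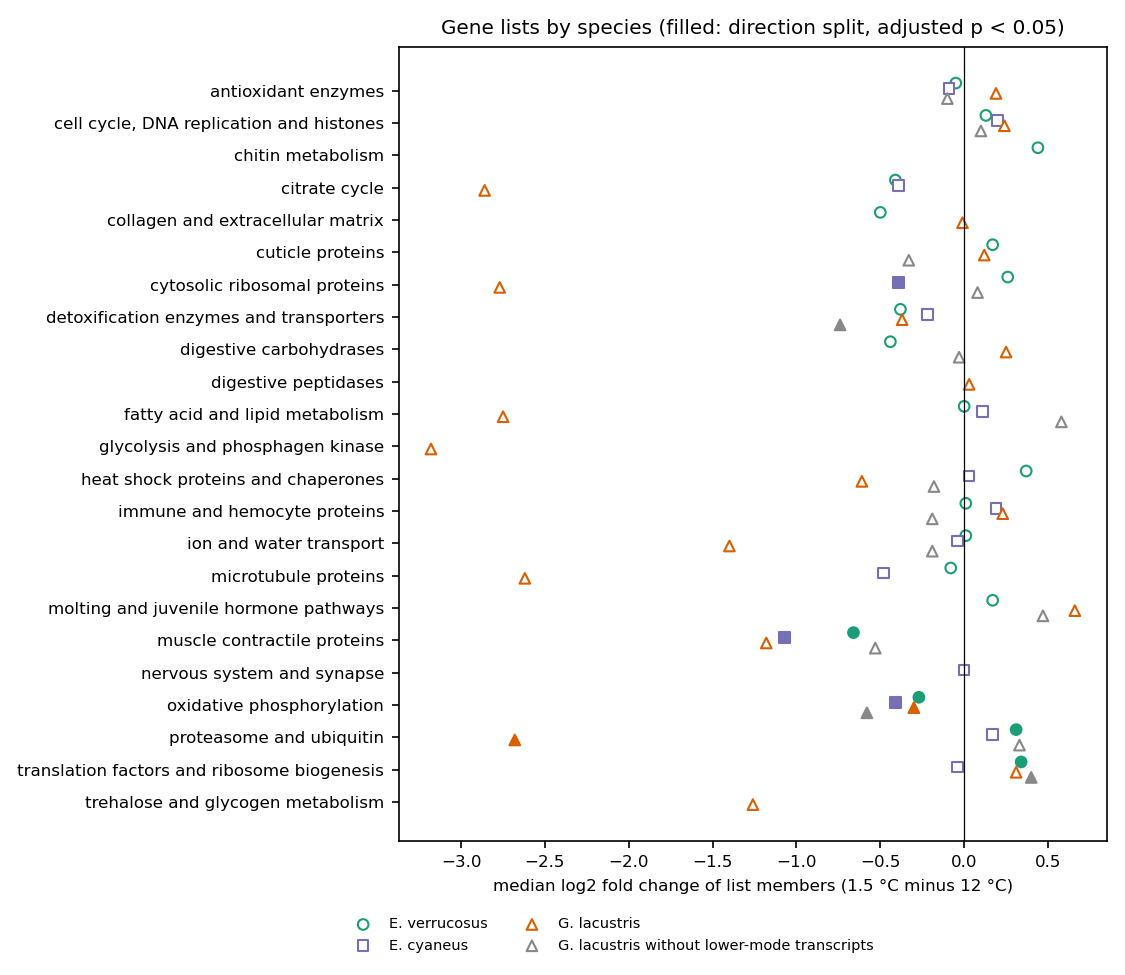
Median log2 fold change (1.5 °C over 12 °C) of the named transcripts of each gene list in each species. Filled coloured symbols passed the direction split at an adjusted p of 0.05 (9 in all). Grey triangles give G. lacustris without the lower mode, a selection made on the outcome, where the proteasome and ubiquitin median moves from −2.68 to 0.33. They are filled by the same rule, for detoxification, oxidative phosphorylation and translation factors.

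The temperature effect on gene groups was compared between species with limma on the mean log2 CPM of 14 lists (42 tests, Benjamini-Hochberg adjustment), and 22 differences passed. Between both Baikal endemics 1 passed: cytosolic ribosomal proteins moved by 0.83 in E. verrucosus and −0.21 in E. cyaneus (difference 1.05, SE 0.36, limma unadjusted p = 0.00768, adjusted p = 0.0161 over all 42 tests). The list held 13 transcripts in E. verrucosus (median log2 fold change 0.26, Fisher's exact test, adjusted p = 0.328) and 36 in E. cyaneus. In E. verrucosus its mean log2 CPM at 12 °C was 1.775 in replicate 4 and 3.60, 2.75 and 2.95 in replicates 1 to 3. In E. cyaneus it was 5.03 in 12 °C replicate 1 and 4.72, 4.59 and 4.09 in replicates 2 to 4. The other 21 set G. lacustris against E. verrucosus (11) or E. cyaneus (10). Proteasome and ubiquitin effects were 0.31 in E. verrucosus, 0.12 in E. cyaneus and −1.80 in G. lacustris (difference from E. verrucosus 2.11, SE 0.23, limma adjusted p = 4.7e-08), microtubule effects were 0.03, −0.30 and −1.87, and citrate cycle effects −0.36, 0.07 and −2.17. Muscle effects were −0.47, −1.03 and −1.20, and the difference between E. cyaneus and G. lacustris did not pass (0.17, SE 0.29, limma adjusted p = 0.61). The muscle effect in E. verrucosus leans on 12 °C replicate 3, with a mean log2 CPM of 7.66 against 6.88, 6.51 and 6.46 in replicates 1, 2 and 4. Without the lower-mode transcripts of G. lacustris limma called 0 of the 42 differences. The difference between both endemics was then also not called, although their own values were unchanged. With all transcripts limma called 9 when each member was scaled to unit variance.

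Few named genes were called in more than 1 species. Names called in both E. verrucosus and G. lacustris were SRSF7 (−1.66 and −1.33), and hnrnpk (1.42 and −2.58) and RAB11A (3.24 and −3.17), which went opposite ways, and TDO2 fell in both E. cyaneus (−1.63) and G. lacustris (−3.20). The G. lacustris transcripts of hnrnpk, RAB11A and TDO2 lie in the lower mode and that of SRSF7 outside it. For E. verrucosus and E. cyaneus the authors' deposited table of each called the same 8 names, 6 in the same direction (cct7, GABRB2, SART1, SELENOH, sls and SULT1C3) and 2 in opposite directions (rpl-9 and RPL35A) (Fisher's exact test of direction, p = 0.464). Between the authors' deposited tables of G. lacustris and E. verrucosus, 23 of 64 shared names had the same direction (Fisher's exact p = 0.107), and with E. cyaneus 30 of 60 did (p = 0.768).

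The authors' deposited tables called 151 names in E. verrucosus, 154 in E. cyaneus and 2943 in G. lacustris. Of those joined to a tested transcript, edgeR called 12 of 50, 7 of 107 and 1083 of 1680 in the same direction. The median difference of log2 fold change, edgeR minus the authors' deposited table, was 0.02, 0.09 and −0.65.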

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

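The tests of both patterns weighed here were chosen after the result was seen, while the tests on other splits of the samples were fixed before.

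A gap between 1 library and the nearest of the others, as a share of the group's range, was unusually large in 5 of 86 groups of 4 libraries, and chance alone gives about 1 in 20. It was 0.961 for the library totals of E. cyaneus at 12 °C, where replicate 3 is the largest, 0.909 for CCT6A in E. verrucosus at 12 °C, 0.851 for BEST3 in E. verrucosus at 1.5 °C, and 0.848 for snrpd2 and 0.864 for RpS27 in G. lacustris at 12 °C.

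The temperature effect on 14 gene lists was compared between species by limma with Benjamini-Hochberg adjustment, and 22 of 42 differences passed. Cytosolic ribosomal proteins differed by 1.05 between E. verrucosus (13 transcripts) and E. cyaneus (36 transcripts). Relative to G. lacustris, E. verrucosus was higher by 1.02 for chaperones, 0.72 for muscle, 0.83 for oxidative phosphorylation, 1.81 for the citrate cycle, 1.10 for lipid metabolism, 2.20 for cytosolic ribosomal proteins, 0.93 for translation factors, 2.11 for proteasome and ubiquitin, 1.91 for microtubules, 0.76 for the cell cycle and 1.24 for ion and water transport. Relative to G. lacustris, E. cyaneus was higher by 0.83 for chaperones, 0.69 for detoxification, 2.24 for the citrate cycle, 1.61 for lipid metabolism, 1.15 for cytosolic ribosomal proteins, 0.71 for translation factors, 1.92 for proteasome and ubiquitin, 1.57 for microtubules, 0.82 for the cell cycle and 1.67 for ion and water transport. Of 100 draws of the temperature labels within species, the real one included, 2 gave as many differences, with 22 in the real grouping and 23 as the highest of the others. Such a count was rare under shuffled labels, but chance is not excluded.

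For transcripts, 1 of the 35 splits of the 8 libraries, the real one, gave as many calls in each species (805 in E. verrucosus with 6 as the highest other, 130 in E. cyaneus with 0 and 10824 in G. lacustris with 0). These gaps argue against chance, at the smallest share that 35 splits allow. For gene lists by the split of directions, the real grouping gave 4 in E. verrucosus (highest other 3, 1 of 35 splits as large), 3 in E. cyaneus (highest other 4, 9 of 35) and 2 in G. lacustris (highest other 4, 8 of 35). The lead of 4 over 3 in E. verrucosus is narrow, and chance is not excluded in any of the species. By camera with a preset correlation and adjustment within each species, the counts were 8 (highest other 5, 1 of 35), 3 (highest other 5, 13 of 35) and 0 (highest other 3, 35 of 35).

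The first pattern is the lower mode of fold changes in G. lacustris, 8078 transcripts whose share of counts was 10.4 to 18.6% at 12 °C and 1.8 to 2.7% at 1.5 °C. A difference in library depth between temperatures is argued against, since the totals overlapped (8569024 to 9721278 at 12 °C and 8501814 to 10176490 at 1.5 °C) and the log2 ratio of their means was 0.03. Normalization was not tested: 1 factor per library moves all transcripts alike, so the choice of factors sets where 0 lies and not the distance between the peaks. Loss of 1 tissue or life stage of the amphipod is also argued against, since 55.0% (95% Wilson interval 47.5 to 62.3) of the named transcripts of 5 lists of genes that every cell uses lay in the lower mode, where a lost tissue would take few of them. A candidate explanation is RNA of another animal in the pools, more of it at 12 °C. Of the motile cilia transcripts 95.8% lay in the lower mode (23 of 24, 95% Wilson interval 79.8 to 99.3). At 12 °C WDR65 lay at 44.3 ± 18.1 CPM and RSPH4A at 28.1 ± 8.75 CPM. Held-out transcripts of the lower mode followed the profile of the rest over libraries of the same temperature with a median coefficient of 0.99. That profile is the median of other lower-mode transcripts drawn at random, so a median near 1 arises with 1 source or several. The coefficient therefore does not tell whether the source was single. A response of the amphipod to temperature in a large set of genes stays open and was not tested, since animals of another species would differ with temperature in the same libraries, and transcript sequences, which could assign transcripts to a species, were not used here.

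The second pattern is the 455 transcripts of E. verrucosus called between temperatures with a group mean under 0.1 CPM, 380 of them near 0 at 1.5 °C. The 2 libraries of lowest total are argued against, since 90.1% were still called without them. Isoforms of 1 assembly gene replacing each other stay open: 369 of the transcripts were the only isoform of their assembly gene in the files, where summing changes nothing, and of the 86 with 2 or more isoforms 79.1% (68) had a summed assembly gene called in the same direction, which decides neither way. Held-out transcripts of the 380 followed a common profile over the 12 °C libraries with a median coefficient of 0.97, against 0.02 for other transcripts of like level, which is consistent with a single source that varied between the warm libraries. Whether these transcripts are a set of amphipod genes silent in the cold, which the design would allow, or RNA from outside the animals was not tested.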

How the results depend on the processing

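The alternatives without the lower mode, without transcripts near 0, without the 2 libraries of lowest total, with fry, camera or the authors' tables for lists, and with adjustment over named transcripts alone were chosen after the result was seen. The split on the authors' tables was the form named in the fixed design, and its place as an alternative was decided then. The count of called transcripts in E. verrucosus (805) was 2253 by DESeq2, 217 with a filter at 5 CPM, 73 at the strict threshold, 4 over named transcripts alone and 196 without the transcripts near 0. In E. cyaneus (130) it was 879 by DESeq2, 28 in a test against a log2 fold change of 1, 4 over named transcripts alone and 0 at the strict threshold in edgeR, where 2936 had an unadjusted p under 0.05. In G. lacustris (10824) it was 16626 by DESeq2, 17735 with no filter, 3691 with a filter at 5 CPM, 2505 at the strict threshold, 1275 over named transcripts alone and 339 without the lower mode. The filters and thresholds change how many transcripts enter, and for DESeq2 the cause was not tested. Leaving out 1 library gave 668 to 912 in E. verrucosus, 41 to 197 in E. cyaneus and 10166 to 12317 in G. lacustris. Other alternatives, such as RLE factors (783, 134 and 11275) and apart from the replicate block below, stayed within 1.5 times the main count.

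Numbers shared between groups did not pair the samples, since same-numbered libraries correlated at −0.21 to 0.06 in E. verrucosus, −0.08 to 0.10 in E. cyaneus and −0.08 to 0.11 in G. lacustris, and not every library correlated best with its own number. With the replicate block edgeR called 170 in E. verrucosus and 44 in E. cyaneus, 34 of them higher and 10 lower in place of 65 and 65, and 9991 in G. lacustris, and it called 2 gene lists in E. verrucosus.

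Of the gene lists called by direction in E. verrucosus (4), 2 were called with 1 transcript per name and 0 with an estimated correlation, and 2 to 3 when 1 library was left out. In E. cyaneus (3) and G. lacustris (2) an estimated correlation also gave 0. In G. lacustris fry called 17 lists and 4 were called from the names of the authors' tables, and leaving out 1 library gave 1 to 2. Those 4 were the immune, microtubule, nervous system, and proteasome and ubiquitin lists. From the names of the authors' tables, oxidative phosphorylation did not pass in E. verrucosus or G. lacustris (Fisher's exact test, adjusted p = 0.139 and 0.362). Nor did cytosolic ribosomal proteins in E. cyaneus (adjusted p = 0.139), while all other lists called by direction in edgeR passed there too. With the filter at 5 CPM the proteasome and ubiquitin list lost its call in E. verrucosus (adjusted p = 0.179) and G. lacustris (0.181). In G. lacustris its median was 0.33 without the lower mode, which held 29 of the 38 members, a reversal fixed by how the mode is defined. Differences between species (22) were 9 with scaled members and 0 without the lower mode in limma. Names called in both tables of a pair of species were 8, 64 and 60 with the authors' tables in place of 0, 3 and 1 in edgeR. For these lists and names the cause was not tested. At the real totals and spread, a simulated 2-fold change was recovered for 0.0% of transcripts in E. verrucosus, 4.0% in E. cyaneus and 2.0% in G. lacustris, and the part of depth in this was not tested.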

Other observations

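The hypotheses on other sources of RNA were tested only after the result was seen.

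Single transcripts of ion transport and the thioredoxin system rose in G. lacustris outside the lower mode, although most called members of their lists fell (ion and water transport 1 rose and 8 fell, 6 of 14 in the lower mode, and antioxidant enzymes 1 rose and 4 fell, such as prdx2 at −3.11). The sodium pump subunit nrv2 rose from 515 ± 75.5 CPM at 12 °C to 880 ± 74 CPM at 1.5 °C (log2 fold change 0.77, SE 0.19, edgeR adjusted p = 0.00768, n = 4 pools), and the thioredoxin reductase TXNRD1 from 90.9 ± 16.4 to 159 ± 29.7 CPM (0.81, SE 0.22, adjusted p = 0.0137). Both calls were lost with TMM factors from the transcripts outside the lower mode (0.36 for each). The cold-shock-domain protein YBX1, in the lower mode, fell from 324 ± 185 to 37.7 ± 9.69 CPM (−3.11, SE 0.40, adjusted p = 3.4e-04). Among 16 named transcripts called in G. lacustris without the lower mode, the disulfide isomerase P4HB (2.75), the leucine sensor SESN1 (1.95) and the neural crest factor SOX10 (2.35) were higher in the cold, and the carbonic anhydrase CA6 (−1.88), SPON2 (−1.66) and the aquaporin AQP12B (−1.38) were lower.

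Some subunits of the chaperonin that folds actin and tubulin were higher in the cold: CCT6A in E. verrucosus (1.51) and CCT5 in G. lacustris (1.61) in edgeR, and cct7 in the authors' deposited tables of E. verrucosus (0.87) and E. cyaneus (0.73), where it did not pass in edgeR (adjusted p = 0.15 and 0.0818). CCT2 went the other way in G. lacustris (−2.65, edgeR adjusted p = 4.5e-04, and −1.93 in the authors' deposited table), where its transcript lies in the lower mode and that of CCT5 outside it. These genes were set side by side after their values were seen, and no test of the group across species was run.

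Motile cilia transcripts, whose products build beating cilia, were summed per library over 39 names in G. lacustris, 26 in E. cyaneus and 6 in E. verrucosus, so that sums are not comparable between species. The sums were 401.6, 223.5, 298.1 and 224.7 CPM in G. lacustris at 12 °C and 33.6, 46.9, 30.2 and 32.9 CPM at 1.5 °C, 34.2 to 42.4 CPM and 14.8 to 31.3 CPM in E. cyaneus at 12 and 1.5 °C, and 0.4 to 1.7 CPM over all libraries of E. verrucosus. In G. lacustris 24 named motile cilia transcripts had a median log2 fold change of −3.43, 0 rose and 23 fell in edgeR (0 rose at an unadjusted p under 0.05 and by DESeq2), and 0 of 24 were positive (Fisher's exact test, unadjusted p = 7.7e-07, and unadjusted p = 0.13 with an estimated correlation). The list was written after the lower mode was seen.

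First principal components held 28.9, 33.2 and 67.1% of the variance in E. verrucosus, E. cyaneus and G. lacustris. In E. verrucosus 1.5 °C replicate 4 (167.3) and 12 °C replicate 1 (93.8) stood apart on the second component, and they were the libraries of lowest total (10187151 and 10537883).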
